A study of Arabidopsis thaliana with 65 samples.

How the data were processed

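Chromatin was profiled in Arabidopsis Col-0 seedlings grown for 12 days at 17 °C in long days and then kept at 17 °C or moved to 27 °C or 37 °C for 15 min, 1 hr or 4 hr. HTA11 (an H2A.Z, FLAG-tagged under its own promoter) was immunoprecipitated from MNase-digested mononucleosomes in 18 libraries of the 27 °C experiment (3 replicates per temperature and time) and 6 of the 37 °C experiment (1 per temperature and time). MNase-seq of the tagged line gave 11 libraries at 27 °C (2 replicates, 1 at 17 °C 1 hr) and 6 at 37 °C, and H3 gave 12 (2 replicates). H2B (2), FLAG-tagged HSFA1A (3) and Pol II (2) had 1 library per temperature after 15 min. Of 65 samples 60 were used, and H2B at 1 hr and 4 hr and the HSFA1A input (5 samples) were not analysed here. One HSFA1A sample is titled 37 °C while its temperature field says 27 °C, and the title was used. The files of the 27 °C H3 replicate 1 at 15 min and at 4 hr carry the word light, which the labels do not explain. Per the labels, sequencing ran on HiSeq2000 and NextSeq500 at several places. Which library was run where is not given, so no batch term was fitted. Replicates are not stated to be separate cultures, so p-values may measure technical spread.

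Per the labels the authors used FastQC, Trimmomatic, Bowtie2, Picard and Salmon (versions not given) with the TAIR10 build. The deposited files hold signal, of a scaling the labels do not state, in 10 bp bins from 500 bp upstream to 500 bp downstream of the transcription start of 17095 genes of 751 to 31258 bp, and 99 of 101 bins were used. The deposited HSFA1A files hold a ratio instead, since their naming and the lack of a single step per library point to a fold enrichment over a background the authors do not state. Of these genes 17020 matched the reference table, which was used for names only, and the printed coordinates are 1-based TAIR10. Bins listed at exactly 0 were read as bins in which no change of coverage starts, not as coverage of 0, and means were taken over bins with a value. The labels do not state this. Of single 0 bins between bins with a value, 52.8% to 94.9% per library (HSFA1A aside) had at least 3 fragments in both neighbours. On coverage simulated under that reading this mean was off by 8.75% at depth 2 and 0.578% at depth 10, against -64.9% and -21.1% with zeros counted. In units of signal, 1 fragment added 0.0185 to 0.193 in HTA11, 0.0147 to 0.115 in MNase and 0.0182 to 0.324 in H3 of the 27 °C experiment. It added 0.0284 to 0.0784 in HTA11 and 0.0193 to 0.0252 in MNase of the 37 °C experiment, 0.0193 to 0.0471 in H2B and 0.0526 to 0.0709 in Pol II. Median window signals were 1.74 to 3.42 in HTA11 and 0.967 to 1.11 in H3. For HSFA1A the step could not be read.

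Window means ran from the start to 200 bp downstream (HTA11, MNase, H3, H2B), 500 bp upstream to the start (HSFA1A) or the start to 500 bp downstream (Pol II). Genes in the lowest 10% of signal were left out, log2 was taken after adding 0.1 times the median (0.218 for HTA11, 0.104 for MNase, 0.106 for H3), and each library was centred on its median. limma (trend, empirical Bayes, two-sided) was fitted to group means in the 27 °C experiment and to temperature with time as a block in the 37 °C experiment, with Benjamini-Hochberg adjustment at 0.05 over genes. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over 15 lists in each contrast, and by exact permutation of temperature within time on the list mean. The 10 fixed lists, with measured of listed genes, were heat shock proteins and co-chaperones (21 of 43), heat shock factors and heat regulators (14 of 18), ambient temperature growth and auxin (28 of 36), circadian clock (14 of 19), cold response (14 of 17), defence (20 of 21), H2A.Z and its deposition (3 of 7), housekeeping (12 of 18), photosynthesis (18 of 28) and rapid stress, touch and jasmonate (13 of 14). The other 5 held the 100 genes with the largest HSFA1A gain at 27 °C or 37 °C, the highest HSFA1A at 17 °C, and the largest Pol II rise or fall. Single libraries were compared with 10000 random lists matched in 20 signal bins. Of the sentinel genes, HSP101, HSP90.1, HSP17.6C, HSFA2, ACT2 and the HSFA1A locus were not measured. Genes and samples, tests, lists and alternatives were chosen before the data were examined, except those named as added.

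Genes are named by a rule set at that point: at 27 °C and 37 °C the 6 largest HTA11 falls and rises past the threshold with 1 direction at 3 times, or the 3 smallest p-values in each direction if none passed. Further named were the 3 largest falls and rises past the threshold in the other fits, the 5 highest and lowest ratios among the top 10% of signal in single-library comparisons, up to 4 list members with the largest change, and the sentinels (HSP70-4, HSP22, MBF1C, PIF4, YUC8, IAA29, FT and UBQ10 among those measured). Genes called at 15 min, and those called with the replicate block or in the libraries of 1 replicate number, were named after their values were seen.

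Whether replicate numbers pair the samples was tested on correlations of library residuals. Same-numbered libraries correlated in all 45 pairs of HTA11 (0.125 to 0.910), 30 of H3 (0.299 to 0.570) and 20 of MNase (0.776 to 0.942), above the limit of 0.1 set beforehand. With 2 replicates the residuals of a group mirror each other, so in H3 and MNase each same-numbered value is repeated and values across numbers add nothing. In HTA11, replicates 2 and 3 also correlated across numbers (-0.102 to 0.780), so its structure is in part replicate 1 against the others. By the limit the numbers pair the samples, and every 27 °C fit is also given with the replicate block. The correlations and the counts with and without the block were computed in the same step, so the counts were visible when that decision was recorded, and it rests on the limit alone. With the block 17 genes passed in HTA11 at 15 min (2 without), 1 averaged over times (0 without) and 8 in the test between times (0 without).

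The steps were tested on simulated data. A change of 0.5, 1 or 2 was given to 200 genes at all 3 times and scored on the average over times. Recovery at a single time was not simulated. The HTA11 fit recovered 10.4%, 64.2% and 98.5% without the block and 38.8%, 94.0% and 100% with it. The H3 fit recovered 4.48%, 49.3% and 75.8% (16.4%, 83.6% and 98.5% with the block) and the MNase fit at 27 °C 0%, 0% and 45.5% (4.48%, 61.2% and 93.9%). The fit of HTA11 relative to MNase recovered 0%, 14.9% and 66.7% (8.96%, 53.7% and 98.5%). The 37 °C fits recovered 1.49%, 56.7% and 100% (HTA11) and 8.96%, 92.5% and 100% (MNase). For these the relative spreads of genes were drawn from the blocked 27 °C HTA11 fit and scaled to the mean of each 37 °C fit. The real HTA11 fit at 37 °C had infinite prior degrees of freedom, so the simulated shares may not describe it. Alternatives tried were no centring, quantile normalization, a pseudocount of 0.5 times the median, no filter, windows to 500 bp and across the start, lists of 50 and 200 genes, each library or time left out, and the replicate block. Added after the data were examined were zeros counted as 0, leaving out the shallowest libraries (1 fragment above 0.15) or the light libraries, lists without centring, and fits of the libraries of 1 replicate number alone. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.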

Results

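Seedlings grown at 17 °C were moved to 27 °C or 37 °C, and the temperature series asks how H2A.Z, nucleosomes, HSFA1A and RNA polymerase II (Pol II) at gene starts respond within 15 min, 1 hr and 4 hr. HTA11, the product of a highly expressed H2A.Z gene, was measured through a FLAG tag, and its signal is given as the mean over the first 200 bp of a gene. Changes are log2 ratios of the warm to the 17 °C libraries, relative to the median over genes of each library.

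The largest early change was at HSP70-4, a cytosolic HSP70 chaperone on chromosome 3 (3991261 to 3993792, minus strand) that is a common reporter of ambient temperature. Its HTA11 signal was 3.68 ± 1.23 at 17 °C and 0.452 ± 0.113 at 27 °C after 15 min (mean ± SD, n = 3 and 3), a change of -2.49 (SE 0.263, adjusted p = 0.000789). HSP90.3, a cytosolic HSP90 chaperone, went from 2.57 ± 0.415 to 0.580 ± 0.179 (-1.79, SE 0.271, adjusted p = 0.0414). These 2 were the genes past the threshold among 15385 tested at 15 min by limma, both lower, and 92 genes had an unadjusted p under 0.05. With replicate number as a block (the replicate block), the count was 17, all lower, with 235 genes at an unadjusted p under 0.05. Among the 17, named because of their calls, were MBF1C, a heat-induced transcriptional coactivator (-1.87, blocked adjusted p = 0.000963; 0.0755 without the block), and HSC70-3, a constitutive cytosolic HSP70 (-1.73, blocked 0.00181; 0.0568 without). ROF1, a peptidyl-prolyl isomerase that binds HSP90, had a change of -1.80 (blocked adjusted p = 0.00704; 0.153 without the block). The rest of the 17 changed by -1.63 to -0.75 and included RANBP1 (-1.46), the plastid chaperonin Cpn60beta2 (-1.35), PDX1.2, a heat-induced protein of vitamin B6 synthesis (-1.45), SGT1A (-1.03), HSP70T-2 (-0.80) and ERDJ3A (-0.92). MBF1C signal fell from 3.57 ± 2.09 to 0.711 ± 0.110 and HSC70-3 signal from 2.64 ± 0.576 to 0.623 ± 0.133 (n = 3 and 3), calls made with the block or over a 500 bp window, where 13 genes passed. HSP70-4 passed in all 18 fits that left out 1 library and missed the threshold without the shallowest libraries (-2.45, adjusted p = 0.0518). HSP90.3 passed in 4 of those 18, the ones without the 17 °C 15 min replicate 1, the 17 °C 1 hr replicate 1, the 17 °C 1 hr replicate 2 or the 27 °C 4 hr replicate 1. HSP90.3 also missed the threshold without centring, with the larger pseudocount, without the filter, across the start and without the shallowest libraries (adjusted p 0.0545 to 1.00).

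**Figure D1:**
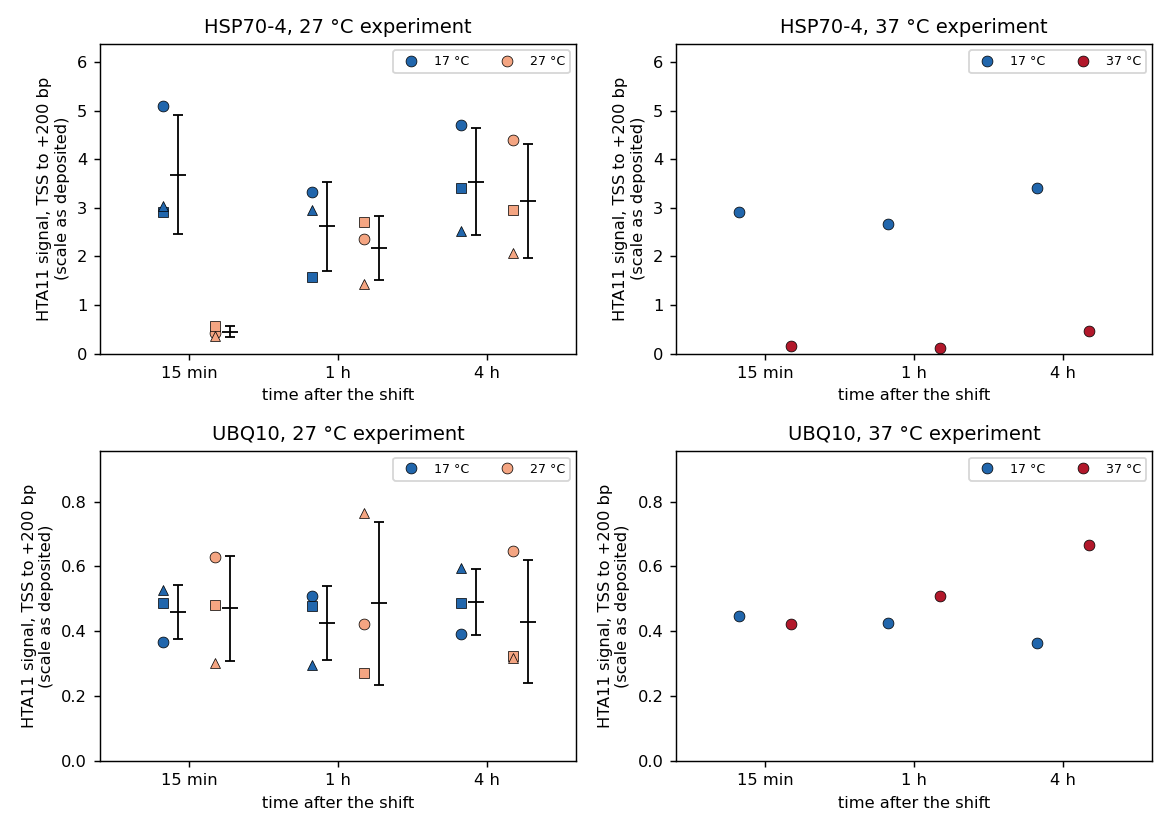
HTA11 signal over the first 200 bp of HSP70-4 and of the reference gene UBQ10 in each library, by time and temperature. Symbols mark replicate numbers, and bars in the 27 °C experiment give mean ± SD of 3 libraries.

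At later times HSP70-4 was near its 17 °C level. It had 2.62 ± 0.924 at 17 °C and 2.17 ± 0.656 at 27 °C after 1 hr, and 3.54 ± 1.10 and 3.14 ± 1.17 after 4 hr (n = 3 in each). Changes of HSP70-4 were -0.06 at 1 hr and -0.32 at 4 hr. By limma, 0 of 15385 genes passed at 1 hr (148 at an unadjusted p under 0.05) and 0 at 4 hr (297), and the replicate block also gave 0 at each (1326 and 1445 at an unadjusted p under 0.05). Averaged over the 3 times 0 genes passed in limma, with 239 at an unadjusted p under 0.05. With the replicate block 1 did, HSP70-4 (-0.95, SE 0.142, blocked adjusted p = 0.0196; SE 0.152 and adjusted p = 0.156 without the block), and 706 had an unadjusted p under 0.05. Behind HSP70-4, the smallest p-values of lower genes belonged to AT5G19120 (-0.73, SE 0.166) and MBF1C (-0.68, SE 0.183), and of higher genes to AT3G57320 (0.38, SE 0.101), AT4G36550 (0.44, SE 0.121) and AT3G57630 (0.55, SE 0.161), none past the threshold. AT5G19120 had 2.99 ± 0.598 at 17 °C and 1.76 ± 1.03 at 27 °C after 15 min, and 1.96 ± 0.319 and 0.826 ± 0.287 after 4 hr (n = 3 in each). At the following sentinel genes averaged changes were near 0 and none passed: PIF4, the bHLH factor of warm-induced growth, 0.01, YUC8, an auxin synthesis gene, 0.00, IAA29 0.01, the flowering signal FT 0.03 and the small chaperone HSP22 0.06. A test of whether the temperature effect differed between times called 0 genes with limma (89 at an unadjusted p under 0.05) and 8 with the replicate block (1095 at an unadjusted p under 0.05). Among them were HSP70-4 (blocked adjusted p = 0.0135), HSC70-3 (0.0167) and HSP90.3 (0.0176).

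Taken as lists fixed before the data were examined, heat shock genes were lower in HTA11 at 15 min. Of 20 measured heat shock protein and co-chaperone genes, 18 were lower in HTA11 at 15 min (median -0.60, camera adjusted p = 2.96e-51; adjusted p = 1.93e-06 with an estimated correlation), 2 passed over all genes and 11 adjusted over the list alone. FES1A, a nucleotide exchange factor of HSP70, went from 2.88 ± 1.04 to 1.18 ± 0.480 (n = 3 and 3). Of 13 heat shock factors and heat regulators, 12 were lower (median -0.24, adjusted p = 2.45e-20; adjusted p = 2.47e-05 with an estimated correlation), 0 over all genes by limma and 5 adjusted over the list alone. HSFB2B, a repressor of heat genes, had -1.86 (adjusted p = 1; 0.0671 with the block), HSFB2A -1.02, and DREB2A, a drought and heat factor, -0.88 (adjusted p = 0.246; 0.0527 with the block), none past the threshold. Averaged over the 3 times, 16 of 20 heat shock protein genes were lower (median -0.24, adjusted p = 3e-12; adjusted p = 0.0023 with an estimated correlation), 0 past over all genes by limma and 1 adjusted over the list alone. So were 11 of 13 heat shock factors (median -0.19, adjusted p = 3.8e-08; adjusted p = 0.0023 with an estimated correlation), 0 and 3. An exact permutation of temperature within time on the list mean per library, over 8000 arrangements and 15 lists, gave p = 0.0855 for heat shock proteins (adjusted p = 0.427) and p = 0.0112 for heat shock factors (adjusted p = 0.169), so neither passed on that test. Averaged medians of the other fixed lists did not pass (adjusted p 0.281 to 0.934): ambient temperature growth and auxin 0.01 (26 genes), circadian clock -0.01 (11), cold response 0.07 (13), defence 0.02 (19), H2A.Z and its deposition machinery -0.08 (3), housekeeping 0.05 (9), photosynthesis -0.08 (10) and rapid stress, touch and jasmonate -0.06 (11). At 15 min their adjusted p-values were 0.114 to 0.791, and no list passed at 1 hr (0.0792 to 0.891) or 4 hr (0.173 to 0.974).

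**Figure D2:**
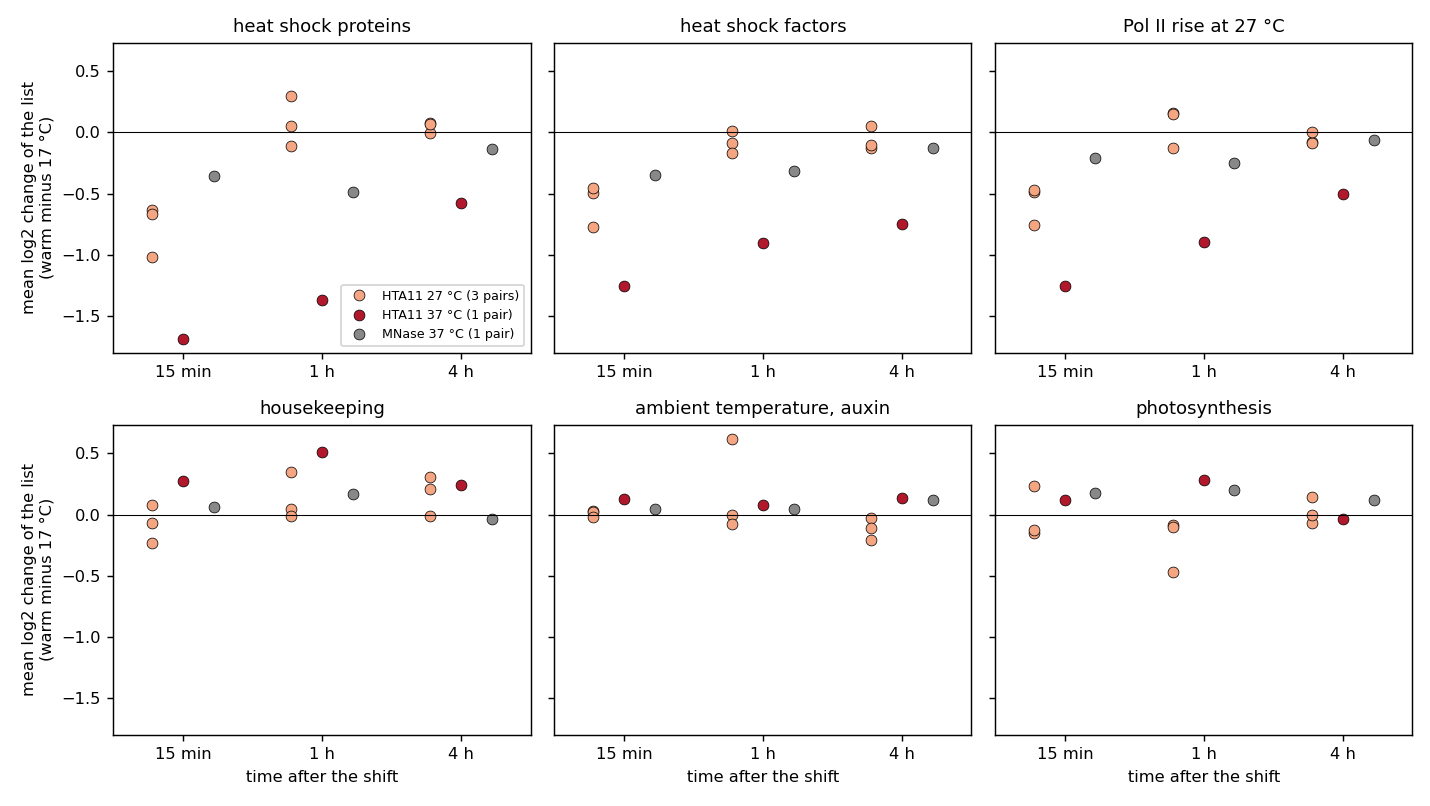
Mean log2 change of 6 gene lists between same-numbered libraries at 17 °C and the warmer temperature, for HTA11 in both experiments and for MNase at 37 °C. Each point is 1 pair of libraries.

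HSFA1A, a heat shock factor that starts the heat response, was measured upstream of the start (500 bp) in 1 library each at 17 °C, 27 °C and 37 °C after 15 min, so only values are given. These are enrichment ratios as deposited, over a background that is not stated, and the 17 °C library is shared by both comparisons. At HSP70-4 the enrichment was 3.79 at 17 °C, 7.80 at 27 °C and 12.0 at 37 °C, ranking second among all genes at 17 °C and highest in both warm libraries. The heat shock protein list had a median of 0.43 at 27 °C (19 of 21 genes higher; 95% of random lists matched on signal lay between -0.14 and 0.25) and 0.79 at 37 °C (20 of 21; matched lists 0.03 to 0.52). Heat shock factors had 0.33 (9 of 14) and 0.81 (14 of 14; matched lists -0.04 to 0.52) at 27 °C and 37 °C. With zeros counted as 0 the heat shock protein medians were 0.65 at 27 °C and 1.07 at 37 °C, and across the start the 37 °C medians were 1.397 for heat shock proteins and 1.48 for heat shock factors. All 4 lay above the central 95% of matched lists, but the size of the median depends on these choices, and how zeros arise was not examined in the HSFA1A files. Across the start other lists also lay outside matched lists, photosynthesis genes at 37 °C (-0.92, 16 of 18 lower) and at 27 °C rapid stress (-0.37) and cold response genes (0.24). With zeros counted as 0 the 3 H2A.Z and deposition genes (0.71 at 27 °C) did too. Ambient temperature growth and auxin genes had 0.22 at 37 °C (20 of 28 higher, percentile 97.56 of matched lists), and 0.28 with zeros counted as 0, inside matched lists (-0.21 to 0.29). Across the start they had 0.20 (23 of 28 higher), above matched lists (-0.17 to 0.16). At 27 °C the highest ratios among well-covered genes were at the cell death suppressor BI1 (1.27), TPR2, a corepressor (1.16), AT2G32520 (1.16), HSFB2B (1.12) and PPa4 (1.10), and the lowest at AT3G15750 (-1.20), AT4G16940 (-1.19), RLP50 (-1.14), AT4G30100 (-1.14) and JAL31 (-1.13). Among genes chosen likewise the highest ratios at 37 °C were at the glutathione transferase GSTU1 (2.98), AT1G30060 (2.66), AT2G25130 (2.45), AT1G03070 (2.42) and the plastid chaperone HSP21 (2.42). The lowest were at AT4G16940 (-2.13), AT4G28230 (-1.69), AT3G15750 (-1.37), AT2G41440 (-1.31) and AT2G39520 (-1.25). HSFA7A (1.87), HSP22 (1.89) and PIF4 (0.89) were higher at 37 °C in that single ratio. By locus number GSTU1 and AT2G25130 are neighbours of the listed heat shock protein genes HSP17.6B and CLPB4. AT1G30060 is a neighbour of AT1G30070, which was lower in HTA11 at 15 min with the replicate block. Whether the 500 bp windows of these genes hold the promoter of the neighbour was not tested. The sample titled 37 °C carries 27 °C in another label field, and the title was used.

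Pol II over the first 500 bp was compared in 1 library each at 17 °C and 27 °C after 15 min. The highest ratio was at AT4G21323, from 0.302 to 7.11 (4.52), a neighbour by locus number of HSA32 in the heat shock protein list. Whether its window takes in signal of that gene was not tested. Heat genes came next. HSP70-4 went from 2.92 to 47.3 (4.21), FES1A from 2.12 to 33.6 (4.17), MBF1C from 3.40 to 45.8 (3.95), and HSFA7A, a heat shock factor, from 2.29 to 26.3 (3.71). The lowest ratios were at AT5G57770 (-3.35), the phosphatase PS2 (-2.84), ATSDI1 (-2.71), AT1G11670 (-2.65) and SRG3 (-2.53). The medians were 0.99 for heat shock proteins (19 of 21 higher) and 1.39 for heat shock factors (11 of 14), above each of 10000 matched random lists. Across the start the heat shock factor median was 0.75, also above each matched list. Rapid stress genes were lower in 13 of 13 (median -1.01), with WRKY40, a wound and defence factor, at -1.97, which lay at the 6.7 percentile of matched lists, and photosynthesis genes in 16 of 18 (-0.59, percentile 61.88). The cold factors CBF1 (-1.71) and CBF2 (-1.68) were lower and COR15A, a chloroplast cold protein, higher (1.75). The cold response list had a median of -0.10 (7 of 14 higher), above the central 95% of matched lists (-1.01 to -0.19, percentile 98.83). PIF4 was at 0.49, YUC8 at -1.06 and IAA29 at -1.09. The median ratio over all genes was -0.22, and ratios are relative to it.

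**Figure D3:**
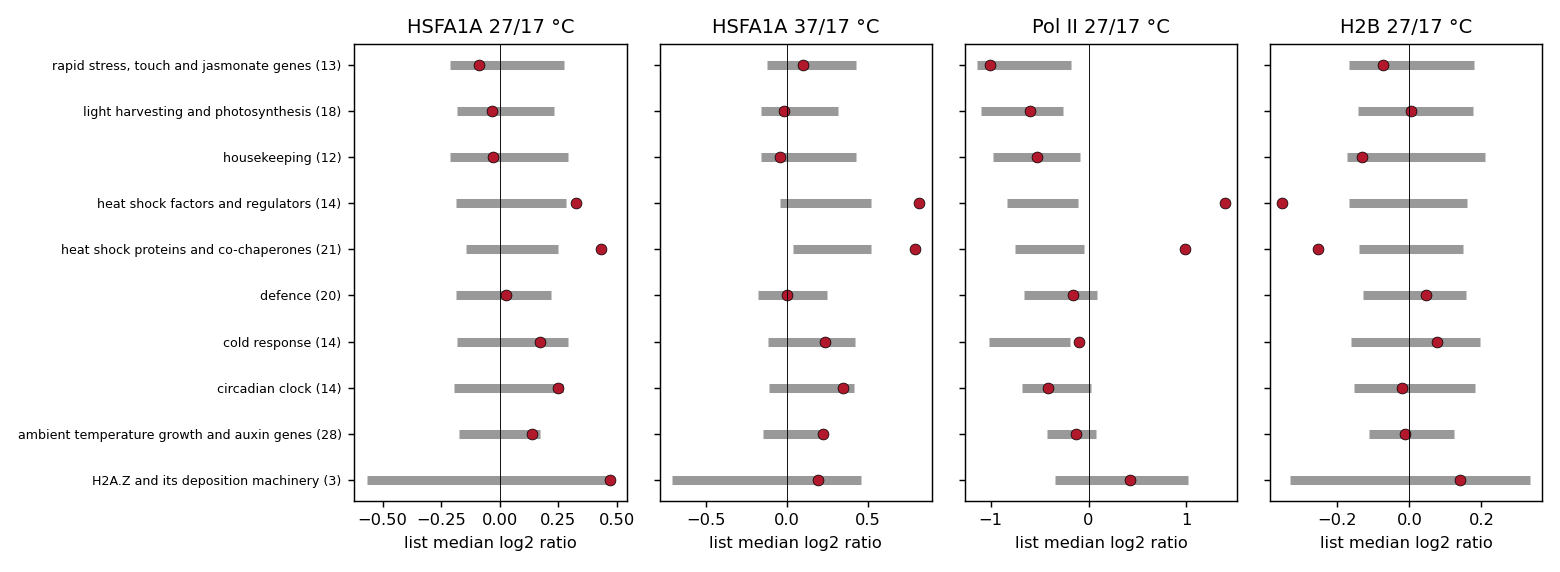
Median log2 ratio of each fixed gene list (points) against the central 95% of random lists matched on signal (bars), in the comparisons with 1 library per temperature.

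Genes chosen from the HSFA1A and Pol II libraries, which are independent of the HTA11 libraries, were then followed in HTA11. Of the 100 genes with the largest Pol II rise, 9 are in the heat shock protein list and 6 in the heat shock factor list. The 82 of them tested had a median HTA11 change of -0.36 at 15 min (69 of 82 lower, adjusted p = 1.06e-77; adjusted p = 5.75e-07 with an estimated correlation; 28 adjusted over the list alone). Averaged over times it was -0.15 (69 of 82, adjusted p = 3.71e-22; adjusted p = 0.000468 with an estimated correlation), with an exact permutation p = 0.0548 (adjusted p = 0.411). Within same-numbered pairs the exact permutation gave p = 0.137 (adjusted p = 0.504, list mean lower in 6 of 9 pairs). The HSFA1A lists overlap these lists too, so their calls are not separate from those of the heat genes. Of 100 genes, the HSFA1A gain at 37 °C shares 7 with heat shock proteins, 3 with heat shock factors and 23 with the Pol II rise. For the gain at 27 °C these were 3, 3 and 8, and for the highest HSFA1A at 17 °C 3, 4 and 7. Genes with the largest HSFA1A gain at 37 °C had -0.10 at 15 min (60 of 93 lower, adjusted p = 3.46e-17; adjusted p = 2.47e-05 with an estimated correlation) and -0.05 averaged (54 of 93, adjusted p = 0.000474; adjusted p = 0.0206 with an estimated correlation). The averaged call was lost without the 17 °C 1 hr replicate 1 (leave-out medians -0.06 to -0.01), the list mean was lower in 4 of 9 pairs, and the exact permutation did not pass (p = 0.123, adjusted p = 0.460). Genes with the highest HSFA1A at 17 °C had -0.07 at 15 min (60 of 86, adjusted p = 7.89e-09; adjusted p = 0.0135 with an estimated correlation) and -0.03 averaged (47 of 86, adjusted p = 0.00603; adjusted p = 0.287 with an estimated correlation; exact permutation p = 0.250, adjusted p = 0.624). Its 15 min call was lost without the 17 °C 15 min replicate 1 (adjusted p = 0.0563), with medians of -0.14 to -0.04 over the fits without 1 library, and its averaged call in 5 of 18 such fits. The HSFA1A gain at 27 °C passed at 15 min with -0.02 (50 of 92 lower, adjusted p = 0.000989; adjusted p = 0.0502 with an estimated correlation) and not when averaged (adjusted p = 0.216). Its median was 0.003 across the start (45 of 92 lower, still past at the preset correlation), 0.03 without the 17 °C 15 min replicate 1 and 0.02 without the 27 °C 15 min replicate 3. Genes with the largest Pol II fall did not pass at 15 min (median 0.01) or averaged (-0.02).

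In the 37 °C experiment HTA11 was low at HSP70-4 and HSP23.6 at all 3 times. HSP70-4 signal was 2.92, 2.67 and 3.41 at 17 °C and 0.156, 0.117 and 0.468 at 37 °C after 15 min, 1 hr and 4 hr, 1 library each (-2.88, SE 0.227, adjusted p = 7.18e-33). HSP23.6, a mitochondrial small chaperone, went from 4.29, 4.19 and 4.25 to 0.325, 0.258 and 1.30 (-2.62, SE 0.191, adjusted p = 1.41e-38). MBF1C changed by -2.43 (SE 0.244), HSP70T-2 by -2.15, FES1A by -1.99 and the galactinol synthase GOLS1 by -1.97 (SE 0.167), and these 6 were the largest falls. HSFB2B and DREB2A changed by -1.85 each. HSP90.3 signal was 2.78, 2.88 and 3.85 at 17 °C and 0.376, 0.842 and 2.68 at 37 °C. HSC70-3 signal was 1.48, 1.91 and 2.04 at 17 °C and 0.193, 0.135 and 2.29 at 37 °C. GOLS1 signal was 4.12, 3.71 and 4.96 at 17 °C and 1.09, 0.772 and 0.974 at 37 °C, and whether these genes differ in time course was not tested. The largest rises were at TFIIIA, the factor of 5S rRNA genes (1.70, SE 0.210, adjusted p = 6.98e-13), AT5G56710 (1.68), the B-box factor STO (1.68), AT3G02468 (1.55), OBP4 (1.44) and EMB3010 (1.42). TFIIIA signal went from 0.222, 0.615 and 1.24 to 1.95, 3.71 and 2.00. In the limma fit with time as a block, 1801 of 15385 genes passed, 778 lower and 1023 higher, 1722 of them in 1 direction at all 3 times. Here the times serve as replicates, with 2 residual degrees of freedom per gene. The prior degrees of freedom that limma estimated were infinite (313 for MNase at 37 °C), so these p-values rest on a variance shared by genes of like signal, hardly on the spread of each gene. In HTA11 1083, 490 and 1200 genes passed without the 15 min, 1 hr or 4 hr libraries. Over a 500 bp window it was 3208, and without centring 705. HSP70-4, HSP23.6, MBF1C and TFIIIA passed in every alternative.

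At the preset correlation heat gene lists were lower and the housekeeping list higher in HTA11 at 37 °C. None of these list calls held with an estimated correlation. That test rests on 2 residual degrees of freedom, and even the Pol II-rise list (-0.81) missed the threshold. Such losses therefore do not tell whether the lists changed. Of 18 heat shock protein genes 16 were lower, and 15 passed over all genes and 15 adjusted over the list alone (median -1.10, camera adjusted p = 6.09e-42; adjusted p = 0.192 with an estimated correlation). Of 13 heat shock factors 12 were lower, and 9 fell past the threshold over all genes and 9 adjusted over the list alone, where 1 also rose (-0.80, adjusted p = 2.69e-22; adjusted p = 0.136 with an estimated correlation). Pol II-rise genes had -0.81 (72 of 79 lower, 52 past over all genes and 56 adjusted over the list alone, adjusted p = 2.37e-67; adjusted p = 0.192 with an estimated correlation). HSFA1A-gain genes at 37 °C had -0.41 (69 of 89 lower, with 39 lower and 3 higher past over all genes and 49 and 4 adjusted over the list alone, adjusted p = 1.7e-30; adjusted p = 0.230 with an estimated correlation), and those at 27 °C -0.04 (adjusted p = 0.00382; adjusted p = 0.344 with an estimated correlation; not past without the 15 min libraries; 0.02 across the start). Genes highest in HSFA1A at 17 °C had -0.11 (adjusted p = 0.00382; adjusted p = 0.192 with an estimated correlation; not past without the 4 hr libraries). Housekeeping genes were higher in 8 of 11, with 4 past over all genes and 4 adjusted over the list alone (0.21, adjusted p = 0.00382; adjusted p = 0.230 with an estimated correlation), with the elongation factor gene EF1A at 1.28 (adjusted p = 1.85e-09) and the glycolytic GAPC2 at 0.77 (adjusted p = 0.00461). The other lists did not pass (adjusted p 0.157 to 0.874), though single members did: the growth regulator PIF5 (0.89, adjusted p = 0.000497), the cold proteins COR47 (-0.73, adjusted p = 0.015) and KIN2 (-0.52, adjusted p = 0.00963), the defence regulators PAD4 (0.79, adjusted p = 0.000332) and WRKY53 (0.65, adjusted p = 0.0065), and ZAT10 (-0.42, adjusted p = 0.0456). PIF4 (0.02), YUC8 (0.16), IAA29 (-0.06), FT (0.01) and HTA11 itself (0.24) did not pass. Across 15054 genes the averaged HTA11 changes of both experiments, which share no library, correlated (Pearson r = 0.460, Spearman rho = 0.449). At 15 min, 1 hr and 4 hr r was 0.273, 0.139 and -0.00139, and genes are not independent replicates. There rho was 0.125, 0.152 and -0.00640, with 52.8%, 55.2% and 50.0% of genes changed in the same direction. Each single time thus gave a lower correlation than the average, and why was not tested.

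Nucleosome signal itself was followed by MNase. At HSP70-4 it went from 1.03, 1.01 and 1.07 at 17 °C to 0.369, 0.196 and 0.692 at 37 °C (-1.22, SE 0.164, adjusted p = 7.76e-09), against -2.88 in HTA11. GOLS1 (-1.12, SE 0.126, adjusted p = 4.59e-13) and HSP23.6 (-0.88, SE 0.129, adjusted p = 3.15e-07) were the next largest falls, and MBF1C (-0.74), HSP22 (-0.81), HSC70-3 (-0.64) and HSFB2B (-0.51) also passed. AT1G19835 (0.76), AT3G09180 (0.76) and the cell wall enzyme gene XTH28 (0.74) had the largest rises. Without the 1 hr libraries XTH28 (0.65), HSP22 (-0.72), HSC70-3 (-0.45) and MBF1C (-0.58) missed the threshold. So did HSC70-3 (-0.61) and HSFB2B (-0.36) without 15 min, HSP22 (-0.76) and HSFB2B (-0.51) without 4 hr, and AT3G09180 and XTH28 (0.28 each) over 500 bp. By limma 83 genes passed, 34 lower and 49 higher, and 56 of them were also HTA11 calls, all 56 in the same direction. From the calls of either assay among the 14570 genes tested in both, 9.11 would overlap by chance if genes were independent. Without the 15 min, 1 hr or 4 hr libraries 35, 51 and 23 passed. Across 14570 genes both changes correlated (r = 0.494, rho = 0.458). Heat shock proteins had a median of -0.33 (15 of 19 lower, 5 past over all genes, 10 adjusted over the list alone, adjusted p = 9.38e-13). Heat shock factors had -0.22 (8 of 12 lower, 3 and 4 past, adjusted p = 8.89e-07), HSFA1A-gain genes at 37 °C -0.09 (adjusted p = 1.24e-06) and Pol II-rise genes -0.10 (70 of 93, adjusted p = 4.34e-12). Defence (0.10, 14 of 20 higher, adjusted p = 0.0261) and photosynthesis genes (0.21, 8 of 9 higher, adjusted p = 0.0229) were higher. For each of these 6 lists adjusted p = 0.259 with an estimated correlation, again on 2 residual degrees of freedom, too few to decide. Defence did not pass without 15 min or 4 hr, and photosynthesis not without 1 hr or 4 hr.

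**Figure D4:**
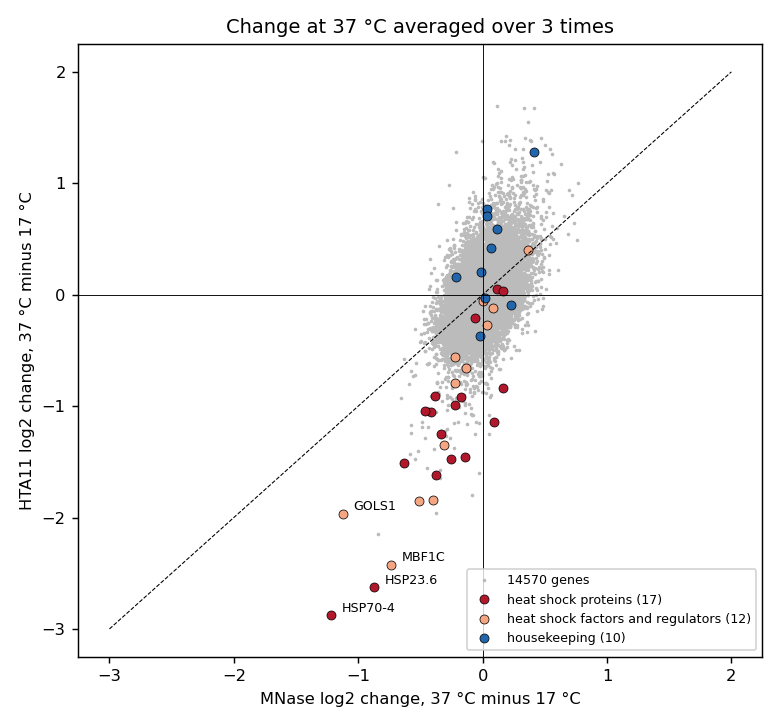
HTA11 change against MNase change at 37 °C for each gene, averaged over 3 times. The dashed line marks equal changes.

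At 27 °C no single gene passed in nucleosome signal, where the MNase fit recovered 0% of simulated changes of 1 and, with the replicate block, 61.2%. MNase signal at HSP70-4 after 15 min was 1.82 at 17 °C and 1.23 at 27 °C in replicate 1, and 0.848 and 0.635 in replicate 2. H3 signal there went the other way, from 1.05 to 1.27 in replicate 1 and from 0.810 to 0.883 in replicate 2. In the 17 °C H3 library of replicate 2 a fragment added 0.324. By limma 0 genes passed in MNase (0 at an unadjusted p under 0.05; 196 with the replicate block, which also called 0) and 0 in H3 (205; 626 with the block, which called 0). The count was 0 of 14414 in the HTA11 change relative to MNase (34; 252 with the block, which called 0). Heat shock protein genes were lower in HTA11 relative to MNase in 17 of 19 (median -0.19, adjusted p = 0.000146; adjusted p = 0.0232 with an estimated correlation) and Pol II-rise genes were in 66 of 78 (-0.19, adjusted p = 2.89e-07; adjusted p = 0.00458 with an estimated correlation), but both medians were 0.04 without centring. That sign follows from the median gene, which shifted by -0.24 in MNase and -0.02 in HTA11. Tested against other genes without centring, the Pol II-rise list still passed (adjusted p = 0.00114) and the heat shock protein list did not (adjusted p = 0.160). In H3 the heat shock protein list was lower in 16 of 21 genes (-0.08, adjusted p = 0.0402; adjusted p = 0.250 with an estimated correlation; exact permutation p = 0.0278, adjusted p = 0.417), a call lost in 7 of 12 fits without 1 library. Within same-numbered pairs the exact permutation gave p = 0.0625 (adjusted p = 0.3125, list mean lower in 5 of 6 pairs). No list passed in MNase (adjusted p 0.132 to 0.938). H2B after 15 min, 1 library each, had 1.26 at 17 °C and 0.582 at 27 °C at HSP70-4 (-0.92), with HSFB2B at -1.02, MBF1C at -0.82 and HSC70-3 at -0.62. Its list medians were -0.25 for heat shock proteins (15 of 21 lower; matched lists -0.14 to 0.15) and -0.35 for heat shock factors (12 of 14 lower). Across the start the heat shock protein median was -0.10 (matched lists -0.09 to 0.09). There clock (-0.23), rapid stress (-0.16), cold response (-0.13) and housekeeping genes (-0.12) also lay below matched lists and photosynthesis genes (0.11) above, so heat shock proteins did not stand apart from these lists there. The highest H2B ratios among well-covered genes were at GLR2.3 (0.81), AT4G19900 (0.73), the floral regulator UFO (0.66), CYP716A1 (0.64) and AMR1 (0.59), and the lowest at MAPKKK19 (-0.69), AT1G25240 (-0.68), AT1G08440 (-0.67), AT5G65170 (-0.64) and TGA6 (-0.62). The MNase replicate 1 libraries were closer to the HTA11 replicate 1 libraries (mean rho across genes 0.738) than to MNase replicate 2 (0.130). What these MNase libraries measure is thus open, and with it MNase and HTA11 relative to MNase at 27 °C throughout. HTA11 replicate 1 was in turn closer to them than to HTA11 replicates 2 (0.663) and 3 (0.486). What sets replicate 1 apart in HTA11 is therefore open as well. The MNase shift was -0.67 at 1 hr, where the 17 °C group holds replicate 1 only. In HTA11 the median gene shifted by -0.17 at 1 hr and 0.14 at 4 hr at 27 °C, and by 0.15 and -0.18 at 37 °C after the same times.

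The shape of the average profile was compared as its highest bin within 200 bp of the start over the mean of the window. The ratio differed between 27 °C and 17 °C by 0.00746 for HTA11 (exact permutation p = 0.949, 18 libraries), 0.0160 for H3 (exact permutation p = 0.870, 12 libraries) and -0.0855 for MNase (exact permutation p = 0.787, 11 libraries), with an adjusted p = 0.949 for each. With the replicate block the exact permutation p-values were 0.816, 0.688 and 0.938, and the MNase difference was -0.00421. Replicate numbers differed more: HTA11 ratios were 1.60 to 2.15 in replicate 1, 1.54 to 1.70 in replicate 2 and 1.33 to 1.42 in replicate 3, and MNase ratios 1.71 to 1.99 and 1.22 to 1.25.

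**Figure D5:**
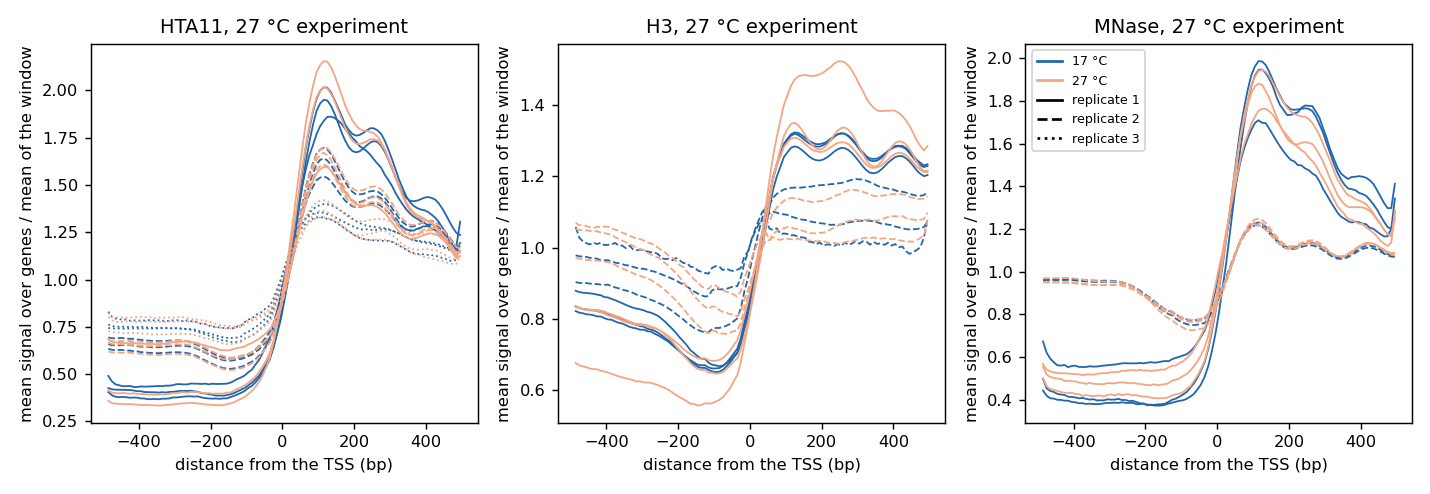
Mean signal over genes around the transcription start in each library of the 27 °C experiment, divided by its mean over the window. Line type marks the replicate number.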

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

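Unevenness of the splits, the tests of 15 min against later times on gene lists, and the comparison of HTA11 with MNase changes at 37 °C, were chosen after the results were seen. Heat genes stood out because their HTA11 change at 27 °C differed between times. The mean change of heat shock protein genes at 15 min minus that at 1 hr and 4 hr was -0.84 (camera adjusted p = 1.35e-29; adjusted p = 3.79e-05 with an estimated correlation). Their mean was -0.78 at 15 min, lower in 3 of 3 same-numbered pairs, and 0.06 later, lower in 2 of 6. Heat shock factors differed by -0.51 (adjusted p = 7.41e-09; adjusted p = 0.00126 with an estimated correlation). Genes with the largest Pol II rise differed by -0.58 (adjusted p = 4.38e-37; adjusted p = 3.40e-05 with an estimated correlation) and genes with HSFA1A gain at 37 °C by -0.26 (adjusted p = 5.01e-10; adjusted p = 0.000495 with an estimated correlation). Smaller differences were at genes with HSFA1A gain at 27 °C, -0.14 (adjusted p = 0.0172; adjusted p = 0.122 with an estimated correlation), and genes highest in HSFA1A at 17 °C, -0.19 (adjusted p = 6.30e-05; adjusted p = 0.0853 with an estimated correlation). With the replicate block and an estimated correlation camera gave adjusted p = 0.149 for the former and 0.0223 for the latter. Housekeeping genes differed by -0.22 (adjusted p = 0.0373; adjusted p = 0.146 with an estimated correlation; adjusted p = 0.0627 with the replicate block). The block kept the other 6 and added rapid stress genes (0.19; adjusted p = 0.0562 without and 0.0403 with the block) and genes with the largest Pol II fall (0.07; adjusted p = 0.0562 and 0.0377), both in the opposite direction. Neither passed with the block and an estimated correlation (adjusted p = 0.193 and 0.250) or on exact permutation (p = 0.155 and p = 0.643). An exact permutation over the 84 ways to choose the early pairs gave p = 0.0119 for each of the other 6 lists and p = 0.0952 for housekeeping. The former is the smallest it can give (adjusted p = 0.0298). Among single genes 8 differed between times with the replicate block and 0 without it: HSP70-4, HSC70-3, HSP90.3, Cpn60beta2, AT1G30070, AT3G53830, MBF1C and AT3G12050.

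The first pattern weighed is the lower HTA11 at heat shock protein genes 15 min after the 27 °C shift. One deviating replicate is argued against, since the list median lay below matched random lists in 3 of 3 replicate numbers (-0.85, -0.48 and -0.52). For loss of whole nucleosomes alone, the HTA11 change minus the MNase change had a median of -0.66 over 19 genes. Of matched lists, 95% lay between -0.18 and 0.13. After 15 min MNase replicate 2 had a flatter profile than HTA11 replicate 2 at both temperatures (highest bin over mean 1.23 against 1.70). The same loss could thus give a smaller log2 fall in MNase, so this test does not exclude loss of nucleosomes, alone or in part. H3 had a list median of -0.09 (6.35 percent of matched lists as low), MNase -0.09 (20.25 percent) and H2B, 1 library per temperature, -0.25 (matched lists -0.14 to 0.15). A loss of HTA11 beyond that of nucleosomes is a hypothesis. The MNase replicate 1 libraries that resembled HTA11 weaken the second test, and where each library was sequenced is not given, so that was not tested.

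The second pattern is the lower HTA11 at the same list in the 37 °C experiment. Weaker enrichment of the 37 °C libraries is argued against, because 0 percent of 10000 random lists matched on 17 °C signal had a median as low as -1.10 (95% of them lay between -0.19 and 0.05). Random lists treat genes as independent, and with an estimated correlation the list call was lost (adjusted p = 0.192). That loss rests on 2 residual degrees of freedom and does not decide the matter. For loss of whole nucleosomes alone, HTA11 minus MNase had a median of -0.88 over 17 genes (matched lists -0.17 to 0.08). After 15 min MNase had a flatter profile than HTA11 at both temperatures here too. The highest bin over mean was 1.31 at 17 °C and 1.16 at 37 °C in MNase, against 1.55 and 1.53 in HTA11. The same loss could thus give a smaller log2 fall in MNase, so this test does not exclude loss of nucleosomes. Temperature, by which the libraries differ, stays a hypothesis that no test here set apart from other differences between single libraries. The list mean was lower in each of the 3 pairs (-1.69, -1.37 and -0.58), with 1 library per temperature and time. Reads shared between chaperone paralogs were not tested.

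The third pattern is signal at the HTA11 locus in the tagged line. Extra copies of the locus, carried as a transgene, would raise the MNase signal of the tagged line over the H3 signal of wild type. Yet the ratio was at the 40.8 and 10.7 percentile of genes in the 2 replicate numbers (log2 ratio -0.26 and -0.42). Such a rise was thus not seen at the start of the gene. The ratio sets different assays against each other at a single locus, without a baseline for that locus. The MNase replicate 1 libraries, whose meaning is open, enter it too. It therefore does not exclude extra copies. No biological explanation was tested.

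Other splits of the libraries were counted. For HTA11 at 37 °C the 10 splits are too few for a share under 0.05: the real one gave 1801 genes and the highest other 22, with 1 of 10 as large. For MNase at 37 °C these were 83 and 0, with 1 of 10 as large. At 15 min at 27 °C 1 of 10 splits was as large (2 genes; highest other 0), and with the block 1 of 4 (17; highest other 0), again too few. At 1 hr and 4 hr the real value and the highest other were 0, so all 10 splits counted, too few again. Averaged over times the real count is 0, so every split is as large by construction and the splits decide nothing for HTA11 (real 0, highest other 5524), H3 (0 and 3069), MNase (0 and 11979), HTA11 relative to MNase (0 and 8853) or the test between times (0 and 2), with 100 of 100 for each. In HTA11, H3, MNase and HTA11 relative to MNase the split with the highest count was the one, or among those, that shared each replicate number least evenly between the temperatures (12, 12, 11 and 15 libraries of difference, against 0, 0, 1 and 1 in the real split). Those single highest counts point to the replicate numbers, a structure of the samples. Over all splits unevenness and count correlated in H3, MNase and HTA11 relative to MNase (rho = 0.386, 0.452 and 0.301) but not in HTA11 (-0.00821), where 3 of 99 splits had calls. With exchanges kept within pairs, where every split parts the same pairs, 11 of 100 gave at least the real 1 (highest other 5), so chance cannot be excluded for the averaged call of HSP70-4.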

How the results depend on the processing

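Zeros counted as 0, leaving out the shallowest or the light libraries, and libraries of 1 number alone were chosen after the data were examined. Of 1447 alternatives over 95 results, 1285 kept direction and side of the threshold (counts within 1.5 times), 80 were weaker, 20 stronger, 36 moved and 26 reversed. HSP70-4 at 15 min kept its call in all but the fit without the shallowest libraries. The cause was not tested unless stated. With an estimated correlation all 37 °C list calls were lost, where 2 residual degrees of freedom are too few for that test to decide. Also lost with it were at 27 °C those of genes highest in HSFA1A at 17 °C (averaged, -0.027), HSFA1A gain at 27 °C (15 min, -0.022) and H3 at heat shock proteins (-0.084). Medians do not change there: HTA11 at 37 °C -1.10 (heat shock proteins), -0.80 (factors), -0.41 and -0.043 (HSFA1A gain at 37 °C and 27 °C), -0.11 (highest), -0.81 (Pol II rise) and 0.21 (housekeeping). In MNase they were -0.33, -0.22, -0.091, -0.10, 0.10 (defence) and 0.21 (photosynthesis). The replicate block gave 17 genes at 15 min, 1 averaged and 8 between times, and changed no other call of these fits or of the lists within a contrast. On the difference of 15 min and later times it lost housekeeping (-0.22) and added rapid stress (0.19) and Pol II fall (0.07). Without centring 1 gene passed at 15 min, 705 in HTA11 and 23 in MNase at 37 °C, and HTA11 relative to MNase reversed to 0.039 for heat shock proteins and 0.038 for Pol II rise, a sign set by the shift of the median gene (-0.24 in MNase, -0.02 in HTA11). Without the filter counts were 1 at 15 min and 148 in MNase at 37 °C, and with the larger pseudocount 1 at 15 min. The 500 bp window gave 13 at 15 min and 3208 in HTA11 in the 37 °C experiment. Across the start HSFA1A gain at 27 °C reversed to 0.0032 at 15 min and 0.018 in the 37 °C experiment. Defence in MNase had 0.056, H3 heat shock proteins -0.022, H2B heat shock proteins -0.10, HSFA1A at 37 °C 1.397 (proteins) and 1.48 (factors) and Pol II at heat shock factors 0.75. With zeros as 0 photosynthesis in MNase had 0.19 (adjusted p = 0.0605), and HSFA1A at heat shock proteins 0.65 and 1.07. Lists of 200 gave 0.0024 (averaged, reversed) and -0.029 (37 °C) for genes highest in HSFA1A. Fewer libraries: without 15 min HTA11 at 37 °C had 1083 genes, MNase 35, HSFA1A gain at 27 °C -0.029 and defence 0.053; without 1 hr 490, 51 and photosynthesis 0.075; without 4 hr 1200, 23, highest HSFA1A -0.075, defence 0.073 and photosynthesis 0.13. H3 heat shock proteins had -0.13 without the light libraries, and 0 genes passed at 15 min without the shallowest ones (87 at an unadjusted p under 0.05, limma). Replicate numbers alone gave 0, 3 and 1 HTA11 genes (24, 1397 and 1099 unadjusted), HSFB2A, J8 and HSP70-4 lower in number 2 and AT1G40104 higher in number 3. H3 heat shock proteins -0.14 and -0.055 (numbers 1 and 2), HSFA1A gain at 37 °C -0.016 and -0.085 (numbers 2 and 3) and highest HSFA1A -0.041 and -0.080 (numbers 2 and 3) did not pass.

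Leaving out 1 library (a lone library in its group is assumed to vary like the others) gave 0 to 1 HTA11 genes averaged, the 1 without the 17 °C 1 hr replicate 2. It gave 0 to 1 between times, the 1 without the 17 °C 1 hr replicate 3. At 15 min counts were 1 to 4, with 4 without the 17 °C 1 hr replicate 1 or 2 and 2 without the 17 °C 15 min replicate 1, the 27 °C 15 min replicate 3 or the 27 °C 4 hr replicate 1. Each other library left 1. At 1 hr, at 4 hr, in H3, MNase and HTA11 relative to MNase counts were 0 to 0. Medians at 15 min were -0.66 to -0.60 (heat shock proteins), -0.32 to -0.20 (factors), -0.48 to -0.36 (Pol II rise), -0.16 to -0.10 (HSFA1A gain at 37 °C), -0.14 to -0.044 (highest HSFA1A, call lost without the 17 °C 15 min replicate 1) and -0.083 to 0.028 (gain at 27 °C). The last reversed without the 17 °C 15 min replicate 1 (0.028) or the 27 °C 15 min replicate 3 (0.015). Averaged they were -0.25 to -0.20, -0.22 to -0.14, -0.18 to -0.13, -0.063 to -0.010 (lost without the 17 °C 1 hr replicate 1, -0.052) and -0.050 to -0.011 (lost without the 17 °C replicate 1 of any time, the 27 °C 15 min replicate 3 or the 27 °C 4 hr replicate 2). Relative to MNase they were -0.27 to -0.12 and -0.26 to -0.17 (heat shock proteins, Pol II rise). H3 heat shock proteins had -0.14 to -0.054, not past without the 17 °C 15 min or 1 hr replicate 1, the 17 °C 4 hr replicate 2, the 27 °C replicate 2 of any time or the 27 °C 15 min replicate 1. Profile differences, none past a test, were -0.0687 to 0.0687 (HTA11), -0.0554 to 0.0873 (H3) and -0.212 to 0.0405 (MNase). MNase without its 17 °C 1 hr replicate 1 could not be fitted. Depth limits what can be seen where 1 fragment adds much, up to 0.324 in H3, 0.193 in HTA11, 0.115 in MNase and 0.0709 in Pol II.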

Other observations

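Several gene groups outside the heat response had values of their own. Of 11 housekeeping genes 4 passed in HTA11 at 37 °C, all higher. The list did not with an estimated correlation (adjusted p = 0.230), a test with too few degrees of freedom there to decide. The 4 genes were EF1A (1.28), GAPC2 (0.77), UBC9 (0.70, adjusted p = 0.00768) and TUB2 (0.59, adjusted p = 0.0205). HSFA1A at EF1A was -1.27 in the single 37 °C ratio. MNase at PAD4, a regulator of salicylate defence, rose by 0.54 at 37 °C (adjusted p = 0.0351), beside an HTA11 rise of 0.79, and BIK1, a kinase of immune receptors, rose in HTA11 by 0.49 (adjusted p = 0.017). Among cold genes KIN1 fell in HTA11 by 0.52 (adjusted p = 0.0474), with an HSFA1A ratio of 1.47, whereas RVE1 (-0.49), a clock factor, and XTH15 (-0.41) did not pass. At 27 °C the largest averaged changes of other lists were BZR1 (0.36), SVP (0.26), PHYB (0.22), RVE8 (0.29), COR15A (0.23), TUB4 (0.28), UBC9 (0.28), TCH4 (-0.25), ERF6 (-0.24) and WRKY53 (-0.22), none past the threshold. ACT7 had -0.77 at 15 min and did not pass. In Pol II at 27 °C the immune receptor FLS2 was at -2.18 and CYP79B2, of indole glucosinolate synthesis, at -2.03, and ARP6, a subunit of the complex that deposits H2A.Z, was listed at 0 at 27 °C. H2B at PIF5 was 0.93 and at WRKY18 -0.78.

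MNase libraries of the 27 °C experiment fell into groups by replicate number. Mean rank correlations across genes were 0.909 within replicate 1, 0.738 between it and HTA11 replicate 1 (0.568 to 0.908), 0.318 with HTA11 replicate 2, 0.130 with MNase replicate 2 (0.0289 to 0.255) and 0.0653 with MNase of the 37 °C experiment. MNase replicate 2 had 0.742 within itself, 0.621 with MNase of the 37 °C experiment and 0.551 with HTA11 replicate 2. HTA11 replicate 1 had 0.663 with replicate 2 and 0.486 with replicate 3, and replicates 2 and 3 had 0.784. After 15 min HSP70-4 went from 5.10 to 0.427 in HTA11 replicate 1 and from 1.82 to 1.23 in MNase replicate 1, and MBF1C from 5.97 to 0.833 and from 3.15 to 1.83. The heat shock protein list had medians of -0.85 and -0.25. The larger falls were thus in the libraries labelled HTA11, as in replicates 2 and 3 (-0.48 and -0.52 for the list), which runs against a plain exchange of labels with HTA11 at 15 min. A different preparation of the MNase replicate 1 libraries was not excluded, and what their values mean is open.

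The HTA11 fit of each replicate number alone, chosen after the data were examined, has the same 6-library design as the 37 °C fit. It called 0, 3 and 1 genes with limma at 27 °C (24, 1397 and 1099 at an unadjusted p under 0.05), where the 37 °C fit called 1801. In these fits the heat shock protein list had -0.34, -0.11 and -0.23, the heat shock factor list -0.21, -0.19 and -0.14 and genes with the largest Pol II rise -0.23, -0.11 and -0.15. Libraries of a 27 °C and of a 37 °C experiment were not compared in 1 fit, so a difference between the temperatures themselves was not tested.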
